A study of Drosophila melanogaster with 5 samples.

How the data were processed

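The series measured polyA RNA of Drosophila melanogaster heads by sequencing in 5 labelled samples, 1 per group: control and Levodopa-fed flies at 25 °C, and control, Levodopa-fed and histone H1 overexpression (H1OE) flies at 29 °C. Levodopa is the precursor that aromatic amino acid decarboxylase turns into dopamine; per the labels' protocols it was given in the food at 4 g/L for 7 days. For H1OE, per the labels' protocols, flies carrying a temperature-sensitive driver of the neuronal gene elav were crossed to an H1 overexpression strain at 18 °C and the offspring were held at 29 °C for 7 days. The 29 °C control is labelled wild type, so the driver and genetic background of H1OE are not matched by label. For that control no cross temperature and no time at 29 °C are given, so rearing temperature and time at 29 °C are not matched by label either. Each sample's group was taken from its labels, and the tissue is named in them both as heads and as brain.

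The authors deposited whole-number read counts per gene for every library. FPKM values, which divide each count by gene length and library size, were also deposited. At 25 °C the deposited FPKM equalled count over exonic length over the column total, and at 29 °C the library size behind the FPKM lay 0.2 to 3.46% below the column total. Alignment used HISAT2 2.2.1 and the genome build was dm6, per the submitters' processing notes; the counting tool, its strand setting and the annotation release were not given in the sources used here. The 25 °C table held 23882 features with 2 columns per sample, and the 29 °C table held 24034 features with 1 column per sample. In the 29 °C table, 2 further columns of values belonged to no sample of this series' labels and were not used here. Gene symbols were taken by identifier from the 29 °C table, because 5 symbols of the 25 °C table had been turned into dates. Of the 29 °C features, 5578 were transposable element insertions.

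Library totals were 25947583 to 30334054 counts at 25 °C and 24770629 to 26832877 at 29 °C. A count of 0 allows up to 3 counts, which is 0.0989 to 0.121 CPM (the count scaled to a fixed library size) per library. These limits and all counting intervals (95%, exact, from the counts of the 2 libraries compared) cover counting error only, since reads without molecular identifiers are not independent molecules.

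At 25 °C the 2 columns of each sample were tested as separate libraries with edgeR's quasi-likelihood F test (TMM scaling), with Benjamini-Hochberg adjusted p of 0.05 and a 2-fold change as thresholds, on 11799 genes with at least 10 counts in 1 library. The labels do not say how these columns relate to separate flies, so the p-values measure only the spread between columns, which may be technical. The spread was small but above counting noise. The variance between columns was 1.99 to 2.76 times the Poisson variance for genes with 20 to 10000 summed counts. For genes above that it was 4.98 times in control and 9.50 times in Levodopa. The common biological coefficient of variation was 2.87%. Counting intervals assume counting noise alone, so they are too narrow for a spread of this size. Standard errors (SE) of log2 fold changes are from this fit, and CPM are means ± SD over 2 columns on TMM-scaled library sizes. In simulated counts with 200 changed genes among 11478, the test called 98% of the 2.5-fold and 99% of the 4-fold changes and 0 of 11278 unchanged genes. These counts had only column-like spread, without variation between fly samples, and changed genes were drawn from those with higher counts. The simulation therefore says nothing about differences between unchanged fly samples. In the data, 6908 of 11799 genes had an edgeR adjusted p under 0.05 before the fold minimum was applied.

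At 29 °C there was 1 library per group, so no test was possible and no p-value is given. A gene passed the size rule when it differed at least 2-fold after 10 counts at the mean library size were added to both libraries (TMM scaling), with at least 10 counts in 1 library. Printed log2 fold changes at 29 °C include these 10 counts, whereas folds are ratios of scaled counts with their counting interval. Fold changes against a library or group at 0 are bounds computed with 3 counts over the group, without the counting error of the other group. In simulated libraries with column-like spread, 195 of 200 genes changed 3-fold passed and 105 of the unchanged genes passed.

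Before the data were examined, 28 gene lists, the named-gene rule, the tests and the main alternatives were fixed. The rule named, among genes with at least 50 counts in 1 group, the 8 largest rises and the 8 largest falls that passed, the 2 members of each list with the largest change, and bmm, Hsl, Akh, ple, Ddc, AkhR and any H1 gene with a read. At 25 °C a named largest rise or fall also had no overlap of columns between groups. Lists with at least 3 measured members were described by the median log2 fold change. The median's percentile was taken among 10000 random lists of the same size, matched on mean expression over 20 expression bins. Outside the central 95% is called outside. Random lists draw genes independently, so percentiles ignore correlation between members. They describe these libraries and are not a test. Of 26 lists, 11 lay outside in Levodopa at 25 °C, 11 in Levodopa at 29 °C and 13 in H1OE. At 25 °C, camera (preset correlation 0.01), camera with an estimated correlation and fry of limma were also run on 26 lists. With 2 columns per group, camera with an estimated correlation has few degrees of freedom. A call missing there therefore says little about correlation between genes. In 100 simulations, unchanged groups were drawn against the shared 29 °C control with a variance of 2.4 times the mean, as between the 25 °C columns, so variation between fly samples is not in these simulations.

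Gene length was related to fold change across genes with a mean of at least 2 CPM, and a version with that trend removed was computed; this was added after the data were seen. Alternatives covered filters on low counts, pseudocounts, fold thresholds, total-count and median-of-ratios scaling, DESeq2, limma-voom, limma on FPKM, replicate columns left out in turn, column number as a block, and FPKM in place of counts. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Coordinates are those of the deposited tables (dm6).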

Results

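PolyA RNA of fly heads was profiled in 5 samples to compare Levodopa feeding with its control at 25 °C and at 29 °C, and neuronal overexpression of histone H1 with the same 29 °C control. The series is concerned with histone H1 and with fat breakdown in flies fed Levodopa. At 25 °C each sample had 2 columns of counts, with totals of 25947583 and 28856401 for control and 30074894 and 30334054 for Levodopa. At 29 °C each sample had 1 column, with 24770629 counts for control, 25975838 for Levodopa and 26832877 for H1OE, so comparisons at 29 °C had no replicate check.

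Histone H1 transcripts were examined first, as the overexpressed gene. The 23 annotated His1 genes, near-identical copies encoding the linker histone, had 0 counts in all 3 libraries at 29 °C, H1OE included, which allows up to 3 counts or 0.112 CPM in H1OE. At 25 °C, 1 count fell on 1 of them in 1 Levodopa column. These libraries did not check the overexpression label: most histone mRNAs lack a poly(A) tail, reads at near-identical copies may go uncounted and a transgene may differ from the annotated copies, and none of these was tested. Of the other histone genes, 5 were measured in Levodopa at 25 °C, 4 in Levodopa at 29 °C and 5 in H1OE, and 0 passed in each comparison. Among them His4r had log2 fold changes of -0.55 (SE 0.02), -0.26 and -0.13.

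Levodopa at 25 °C was accompanied by lower transcripts of mitochondrial energy metabolism and translation. Of 69 measured nuclear genes of oxidative phosphorylation, the pathway of the respiratory chain and ATP synthase, 18 fell and 0 rose. The complex I subunit gene ND-B12 went from 130 ± 6.54 to 59.1 ± 2.76 CPM (SD, n = 2 columns), and ATPsynO from 594 ± 5.31 to 278 ± 7.78 CPM. Of 85 cytoplasmic ribosomal protein genes 21 fell and 0 rose, among them RpLP2 (log2 fold change -1.19, SE 0.02) and RpS14b (-1.17, SE 0.03). Fatty acid oxidation genes followed the same direction, with 6 of 24 lower, including the acyl-CoA oxidase gene Acox57D-d (-1.21, SE 0.13) and the medium-chain acyl-CoA dehydrogenase gene Mcad (-1.17, SE 0.06). The median log2 fold changes of these lists, -0.92, -0.89 and -0.81, lay below those of all 10000 random lists, also with the length trend removed. The calls of single members sat close to 2-fold: with the trend removed 0, 0 and 1 members of these 3 lists fell, with total-count scaling 0, 3 and 3, and with a filter of 50 counts 13, 11 and 5, the list medians staying negative (-0.45, -0.45 and -0.55 with the trend removed).

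The call of camera for oxidative phosphorylation had an adjusted p of 2.89e-18 with the preset correlation, and adjusted p = 0.306 with an estimated correlation. For the ribosomal list these were 2.46e-24 and adjusted p = 0.424 with an estimated correlation, and for fatty acid oxidation 1.06e-07 and adjusted p = 0.306 with an estimated correlation. The mitochondrial genome itself took 12.98 and 13.24% of counts in the control columns and 19.2 and 19.98% in the Levodopa columns. Much of this was the ribosomal RNA mt:lrRNA, with 6.10 and 6.26% in control and 10.33 and 10.95% in Levodopa. Of 16 measured mitochondrial genes 0 passed the thresholds (median 0.35). Fold change also followed gene length across 9083 genes (Spearman's rho 0.637, genes not being independent replicates): genes in the lowest length quartile, with a median length of 960 bases, had a median log2 fold change of -0.51, and those in the highest, with 5520 bases, one of 0.38.

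Antimicrobial immunity split at 25 °C. Of 42 measured genes 13 fell and 6 rose, and with the length trend removed 6 fell and 8 rose. Transcripts of the Toll-pathway target Drs, the antifungal peptide drosomycin, fell from 354 ± 6.95 to 31.5 ± 0.57 CPM, and BomBc1, another Toll target, fell from 48.7 ± 2.44 to 5.35 ± 0.33 CPM. Some genes of the antibacterial peptides diptericin and attacin rose, with log2 fold changes of 1.96 for DptA (SE 0.05), 1.16 for DptB (SE 0.04), 1.76 for AttC (SE 0.10) and 2.89 for AttD (SE 0.52). Dro (-1.44, SE 0.05) and AttB (-1.25, SE 0.06) fell, and AttA (-0.65, SE 0.14) did not pass. The list median was -0.42, at percentile 0.09 (-0.16 and 0.98 with the length trend removed), and camera gave adjusted p = 0.0288, with adjusted p = 0.416 with an estimated correlation. Among fat body markers, Lsp2, a larval serum protein gene, rose from 0.586 ± 0.202 to 5.11 ± 0.18 CPM, while Obp99b and Cyp4g1 fell by 2.82 and 4.05 on the log2 scale. The 12 markers had a median of -0.70 at percentile 0.14, and of -0.45 with the length trend removed (camera adjusted p = 0.032, and adjusted p = 0.493 with an estimated correlation).

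Lipid genes gave a mixed picture at 25 °C. Of 26 lipid storage and lipolysis genes 1 rose and 3 fell. Lsd-1, which encodes a perilipin on the lipid droplet surface, fell from 494 ± 2.14 to 167 ± 1.42 CPM, AkhR, the receptor of adipokinetic hormone, from 130 ± 7.28 to 58.7 ± 1.03 CPM, and CG6283 by 3.39 on the log2 scale. Dgat2, a diacylglycerol acyltransferase gene, rose by 1.34 (SE 0.25, adjusted p = 1.49e-07). The lipase genes bmm (log2 fold change 0.48, SE 0.06) and Hsl (0.13, SE 0.06) and the hormone gene Akh (0.77, SE 0.08) did not reach 2-fold. Fatty acid synthesis genes had 0 of 21 past the thresholds (median -0.21, and -0.45 at percentile 0.03 with the length trend removed). Camera gave them adjusted p = 0.0483, and adjusted p = 0.433 with an estimated correlation. Of 16 lipid carrier genes 0 passed (median -0.29).

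Synaptic genes shifted upwards by less than 2-fold. All 30 synaptic and neuronal genes had a positive log2 fold change, 0 of them past 2-fold, with Syn at 0.70 (SE 0.03) and unc-13 at 0.67 (SE 0.02). Their median of 0.47 lay above all 10000 random lists, and with the length trend removed it was 0.08, at percentile 99.3 (camera adjusted p = 1.18e-09, and adjusted p = 0.306 with an estimated correlation). Serotonin and octopamine genes (0 of 17 past the thresholds, median 0.33) and clock genes (0 of 15, median 0.35, with tim at 0.99, SE 0.04, and per at 0.85, SE 0.06) lay at percentiles 99.8 and 98.6, and at 72.3 and 78.4 with the length trend removed. Camera gave the serotonin and octopamine list adjusted p = 0.0215, and adjusted p = 0.416 with an estimated correlation, and did not call the clock list (adjusted p = 0.284). With DESeq2, total-count scaling or a filter of 50 counts tim passed. Among 27 neuropeptide genes (median -0.01, and 0.34 with the length trend removed) Dh44 alone passed (1.27, SE 0.06), and Ilp2 stood at -0.98 (SE 0.04). The dopamine synthesis gene ple, encoding tyrosine hydroxylase, had a log2 fold change of 0.82 (SE 0.04), Ddc one of -0.03 (SE 0.06), whereas e and b were lower (-0.90 and -0.88, SE 0.04 each). Of 21 dopamine and pigment genes 0 passed, with a median of -0.25 at percentile 16.2.

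A few stress and detoxification genes changed. Of 18 heat shock genes 3 copies of Hsp70 rose, Hsp70Ba (1.39, SE 0.34, adjusted p = 7.3e-05), Hsp70Aa and Hsp70Bb, whose reads cannot be assigned with certainty between copies. That list had a median of 0.30 at percentile 98.0 (camera adjusted p = 0.0483, and adjusted p = 0.504 with an estimated correlation). Of 47 detoxification genes GstD5 rose from 0.648 ± 0.453 to 7.83 ± 0.578 CPM, and GstE9 (-1.24, SE 0.03) and Sod2 (-1.02) fell. Their median of -0.30 lay at percentile 3.10, and at 73.5 with the length trend removed (camera adjusted p = 0.0186, and adjusted p = 0.416 with an estimated correlation). The metallothionein gene MtnE rose from 0.928 ± 0.285 to 9.90 ± 0.421 CPM. In the insulin, AKH and starvation list (22 genes, median 0.43, percentile 99.8) tobi rose by 1.16 (SE 0.15) and AkhR fell, and camera did not call the list (adjusted p = 0.239). Of 14 digestive genes LysP alone fell (median -0.67, percentile 0.00, camera adjusted p = 0.0641), of 14 haemocyte genes PPO1 (-1.17, SE 0.04) and NimB4 (-1.15, SE 0.08) fell, and of 14 glial genes gcm rose by 2.09 (SE 0.92) on few counts, a call that DESeq2 did not make.

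In 5 further lists 0 members passed at 25 °C: 24 phototransduction genes (median -0.34, with Rh6 at -0.98), 25 chromatin acetylation and silencing genes (0.07), 20 muscle genes (0.16), 4 Turandot genes (-0.22) and 6 ovary genes (-0.02). The phototransduction median lay at percentile 36.5 while camera called the list lower (adjusted p = 0.0288, and adjusted p = 0.416 with an estimated correlation). Of 2 testis genes and 3 male X dosage genes 0 passed, with lncRNA:roX1 at 0.50. For each list, counts of changed genes adjusted over the list alone equalled those over all genes tested. They were 18 for oxidative phosphorylation, 21 for ribosomal proteins, 19 for antimicrobial immunity and 6 for fatty acid oxidation. With 6908 of 11799 genes at an edgeR adjusted p under 0.05, the 2-fold minimum decided most calls. The equality is therefore no separate support.

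The largest falls at 25 °C were near-complete. CG16826 (2L, 13347773 to 13349020) went from 1929 ± 18.5 to 0.11 ± 0.112 CPM, and whe (X, 21402339 to 21402772) from 14926 summed counts to 1, a 1.81e+04-fold difference with a counting interval of 3250 to 7.15e+05. CG45080, CG30371, CG13947, CG44142 and CG43679 went to 0 counts, at least 1186-fold, 689-fold, 662-fold, 272-fold and 182-fold lower. CG33109 went from 2516 counts to 2. The largest rises were CG40439 (4.53, SE 0.26, adjusted p = 1.73e-67), GstD5, MtnE, Lsp2, CG16898 (3.01, SE 0.08), AttD, the transposable element insertion FBti0018951 (2.83, SE 0.20) and Ugt37A3 (2.72, SE 0.19). In all, 238 genes rose and 371 fell among 11799 tested with edgeR, 157 and 307 with DESeq2, and 536 and 127 with the length trend removed, which turned the balance. Total-count scaling raised every log2 fold change by 0.139 and gave 356 higher and 208 lower. The number of rises also fell to 137 and 153 with the second or the first Levodopa column left out, and to 105, beside 324 falls, under the size rule on summed columns.

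Levodopa at 29 °C was accompanied by lower antimicrobial and fat body transcripts and by higher Hsp70. Of 38 antimicrobial genes 17 fell past the size rule and 0 rose. DptB went from 2435 counts to 17, 155-fold lower (counting interval 96.9 to 267), DptA from 1008 to 7, 156-fold lower (75.5 to 390), AttC from 6267 to 104, 65.4-fold lower (53.9 to 80.1), and edin from 56 to 0, at least 20.3-fold lower. Mtk, AttB and Dro were 25.2-fold, 9.61-fold and 9.33-fold lower. The list median of -0.64 lay below all 10000 random lists.

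Of 14 fat body and yolk markers 6 fell and 1 rose in Levodopa at 29 °C (median -0.58, percentile 0.00). Lsp1alpha, a larval serum protein gene, was 24.0-fold lower (19.6 to 29.7), the yolk protein gene Yp1 6.06-fold lower (4.23 to 8.89) and fit, a gene of the female fat body, 5.01-fold lower (4.47 to 5.62), while Fbp1 rose on 1 count in the control and 18 in Levodopa. The Lsp genes are paralogs that can share reads. Among 4 Turandot stress genes TotC and TotM fell (median -0.82, percentile 0.00). Of 7 digestive genes the amylase gene Amy-p was 6.13-fold lower, with its near-copy Amy-d at a log2 fold change of -0.60 (list median -0.54, percentile 0.03).

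Of 19 heat shock genes 3 rose at 29 °C (median 0.28, above all random lists): Hsp70Bbb was 4.78-fold higher (3.87 to 5.94), Hsp70Bc 2.54-fold and Hsp70Bb 1.00 on the log2 scale, near-copies with uncertain assignment of reads. Of 45 detoxification genes Cyp6a8 (2.80-fold) and Cyp6g2 rose and Cyp4e3 fell (median -0.11, percentile 0.17, and 34.8 with the length trend removed). The other largest rises were CG17715 (4.97-fold, 3.70 to 6.77), Dlip1, Ttc26, eIF4B and CG31272. In the insulin, AKH and starvation list tobi fell among 20 genes (median -0.17, percentile 0.13).

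Energy and lipid lists moved little in Levodopa at 29 °C. Members past the size rule numbered 0 of 66 in oxidative phosphorylation, 0 of 85 in ribosomal proteins and 0 of 24 in fatty acid oxidation, with medians of -0.11, -0.10 and -0.15 that lay outside the random lists. With the length trend removed the first of these lists was at percentile 52.2 and the ribosomal list at 97.9, on the other side. In the fatty acid synthesis list of 21 genes only fit fell (median -0.11, percentile 2.17), the female fat body gene already counted among the fat body markers. Of 25 lipid storage genes CG6283 fell, 4.73-fold (2.61 to 9.15). The log2 fold changes of bmm, Hsl, AkhR, ple and Ddc were -0.24, -0.03, 0.08, 0.09 and -0.03, and Akh had 7 counts in the control and 5 in Levodopa, too few for the comparison.

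The remaining lists lay inside the range of random lists in Levodopa at 29 °C, with 0 members past the size rule among 30 synaptic, 25 neuropeptide, 17 serotonin and octopamine, 15 clock, 13 glial, 24 phototransduction, 21 dopamine and pigment, 25 chromatin, 16 lipid carrier, 20 muscle, 14 haemocyte and 3 male X dosage genes. Of 5 ovary genes yellow-g rose, and the 1 testis gene measured did not pass. In all, 126 genes were higher and 169 lower among 11145 compared, the balance turning to 171 and 118 with the length trend removed. Simulated unchanged libraries with the spread of the 25 °C columns gave 85.6 genes past the same rule on average; they hold no variation between fly samples, so this is no expected count for 2 unchanged samples.

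H1OE was accompanied by much lower fat body, Turandot and antimicrobial transcripts than the control. Of 12 fat body and yolk markers 9 fell and 0 rose (median -1.96, below all random lists): Lsp1alpha was 271-fold lower (142 to 593), fit 158-fold (90.2 to 306), Lsp2 25.8-fold (24.2 to 27.6) and Lsp1beta, with 144478 counts in the control and 8571 in H1OE, 19.1-fold (18.7 to 19.6). All 4 measured Turandot genes fell (median -2.02), TotX 5.87-fold and TotA 5.12-fold. Of 38 antimicrobial genes 13 fell and 3 rose (median -0.53, below all random lists). AttC was 142-fold lower (108 to 192), DptA 60.2-fold (38.4 to 101) and PGRP-SC2, which encodes an amidase that degrades peptidoglycan, 32.0-fold (24.7 to 42.3). The Toll targets Drs, BomS2 and BomBc1 rose, with log2 fold changes of 1.90, 1.75 and 2.71.

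Hormone genes of H1OE heads fell as well. Of 25 neuropeptide genes 6 fell and 0 rose (median -0.34, percentile 0.00), among them the insulin-like peptide gene Ilp2, from 1834 counts to 361 (5.77-fold, 5.15 to 6.47), Ilp3, Ilp5, Hug (4.24-fold) and CCHa2. In the insulin, AKH and starvation list 5 of 20 fell and 2 rose (median -0.15, percentile 3.04). Pepck2, a gene of gluconeogenesis, was 13.3-fold lower (11.9 to 14.9), tobi was 6.75-fold lower, and Thor, the 4E-BP gene that foxo activates, and InR rose by 1.94 and 1.02 on the log2 scale. The dopamine and pigment list had AANAT1 lower among 21 genes (median -0.13, percentile 3.21), with ple at -0.78 and Ddc at -0.11.

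Lipid genes in H1OE went in both directions. Of 25 lipid storage and lipolysis genes mag, a lipase gene, rose and Lsd-1 and CG6283 fell, with log2 fold changes of 6.06, -1.33 and -2.10 (list median 0.00, percentile 53.3). The reads of mag (3L, 20460683 to 20462274), 13 in the control and 1678 in H1OE, lie within atk (3L, 20454690 to 20464862), which was 10.4-fold higher (9.11 to 11.9); the strand of counting is not given, so the 2 genes' reads are not separable here. The lipase gene bmm was 1.47-fold higher (1.42 to 1.53) and did not pass, Hsl was at 0.01 and AkhR at -0.76. Of 24 fatty acid oxidation genes 0 passed, with a median of -0.47 below all random lists, and CRAT and yip2 were at -0.83 and -0.79. In the fatty acid synthesis list of 22 genes sug and fit fell and bgm rose (median -0.31, percentile 0.04), fit being the fat body gene already counted above. Of 16 lipid carrier genes 2 fell, Acbp2 among them at 2.55-fold (median -0.36, percentile 0.04). Oxidative phosphorylation genes had 0 of 66 past the rule and a median of -0.33, below all random lists, and 0 of 85 ribosomal genes passed (median 0.03).

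Heat shock genes rose in H1OE in 5 of 19 cases (median 0.68, above all random lists), Hsp67Bc 3.44-fold (2.72 to 4.38) and Hsp70Ab 3.09-fold (2.55 to 3.75). Detoxification genes fell in 8 and rose in 3 of 45 cases (median -0.28, percentile 0.00), Cyp4e3 7.24-fold lower and Cyp6a2 higher by 1.82 on the log2 scale. Of 10 digestive genes 2 rose and 2 fell (median 0.37, percentile 99.1), the direction of the median turning to -0.12 with a filter of 50 counts. The largest other rises were CG31683, from 16 counts to 1035 (57.0-fold, 34.9 to 100.1), the transposable element insertion FBti0019110, from 0 to 208 (at least 61.1-fold), CG11425 (11.9-fold), Cyp4p2 (11.2-fold), phr (9.85-fold) and lncRNA:CR46216, from 3 counts to 103 (30.2-fold, 10.1 to 149).

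In H1OE the synaptic list had 0 of 30 genes past the size rule and a median of 0.14 at percentile 99.8, and at 93.1 with the length trend removed. Of 14 haemocyte genes 0 passed, with a median of -0.18 at percentile 2.27. Inside the random lists lay the chromatin list, in which Nap1 alone rose (2.37-fold) among 25 genes, clock genes, in which to alone fell (3.01-fold) among 15, muscle genes, in which TpnC41C alone fell among 20, ovary genes, in which vas alone rose (8.37-fold, 3.62 to 23.8) among 6, and serotonin and octopamine, glial, phototransduction and male X dosage genes, of which 0 of 17, 14, 24 and 3 passed. The 1 testis gene measured did not pass. In all, 380 genes were higher and 428 lower among 11340 compared. The balance turned to 456 and 350 with the length trend removed, and to 416 and 374 with total-count scaling. Simulated libraries with the spread of the 25 °C columns, again without variation between fly samples, gave 85.7.

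**Figure D1:**
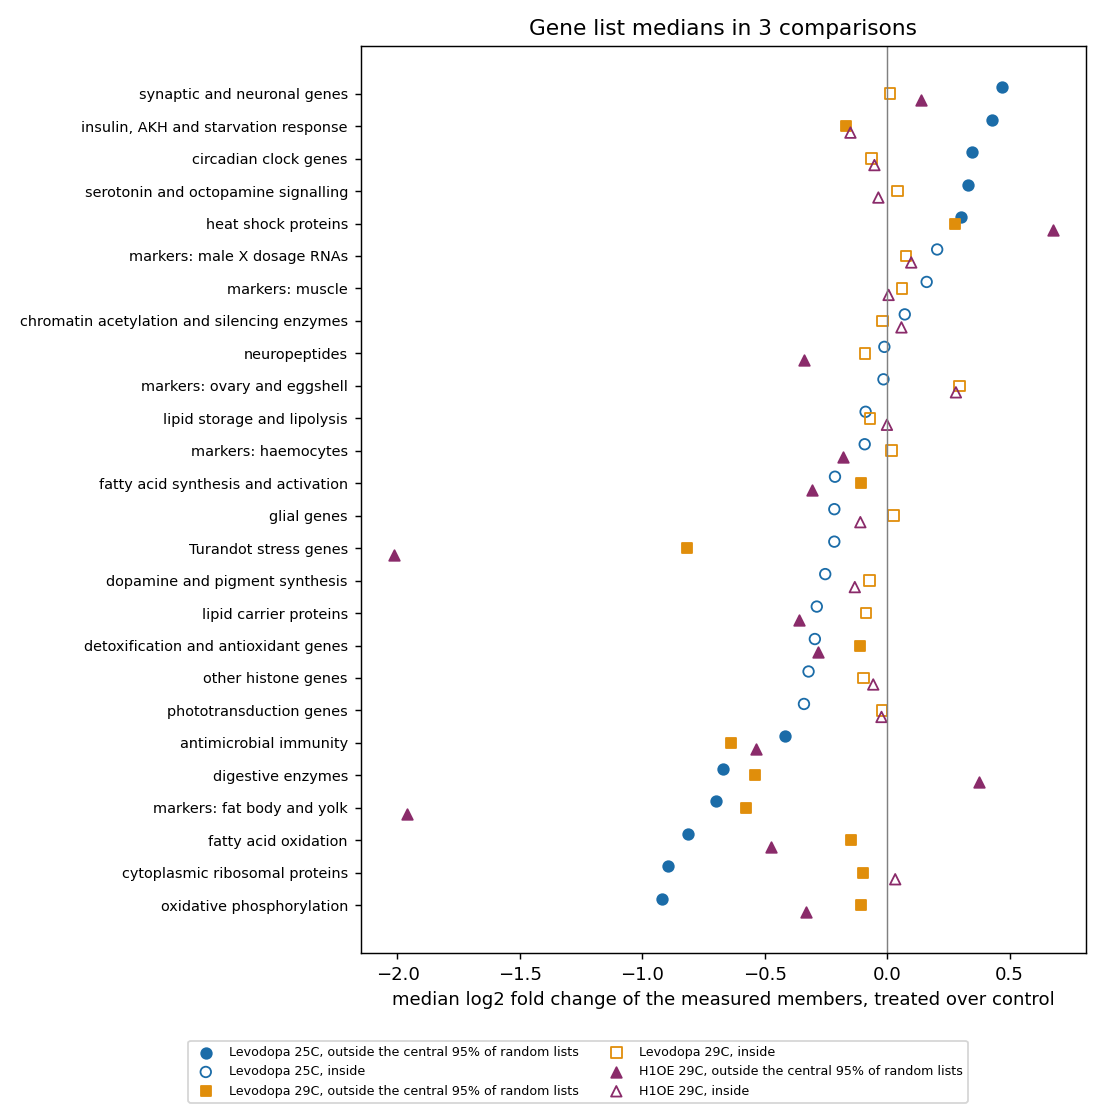
Median log2 fold change of each gene list (x axis, treated over control) in Levodopa at 25 °C (circles), Levodopa at 29 °C (squares) and H1OE at 29 °C (triangles). Filled symbols lie outside the central 95% of 10000 random lists; the fat body list stands at -0.70, -0.58 and -1.96.

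Chemosensory receptor genes stood apart in H1OE. This group was chosen after its values were seen and was not among the fixed lists. Of 26 odorant (Or) and ionotropic (Ir) receptor genes with at least 50 counts in 1 library, 12 fell past the size rule, 0 rose and 14 did not pass. The co-receptor genes Orco, Ir76b, Ir25a and Ir8a, which partner with many tuning receptors, went from 1847 to 412, 481 to 22, 380 to 62 and 168 to 10 counts. Or59b was 19.3-fold lower (11.7 to 34.2), while Ir62a and Or43b had log2 fold changes of 0.35 and -0.30. In each Levodopa comparison 0 of the 26 passed.

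**Figure D2:**
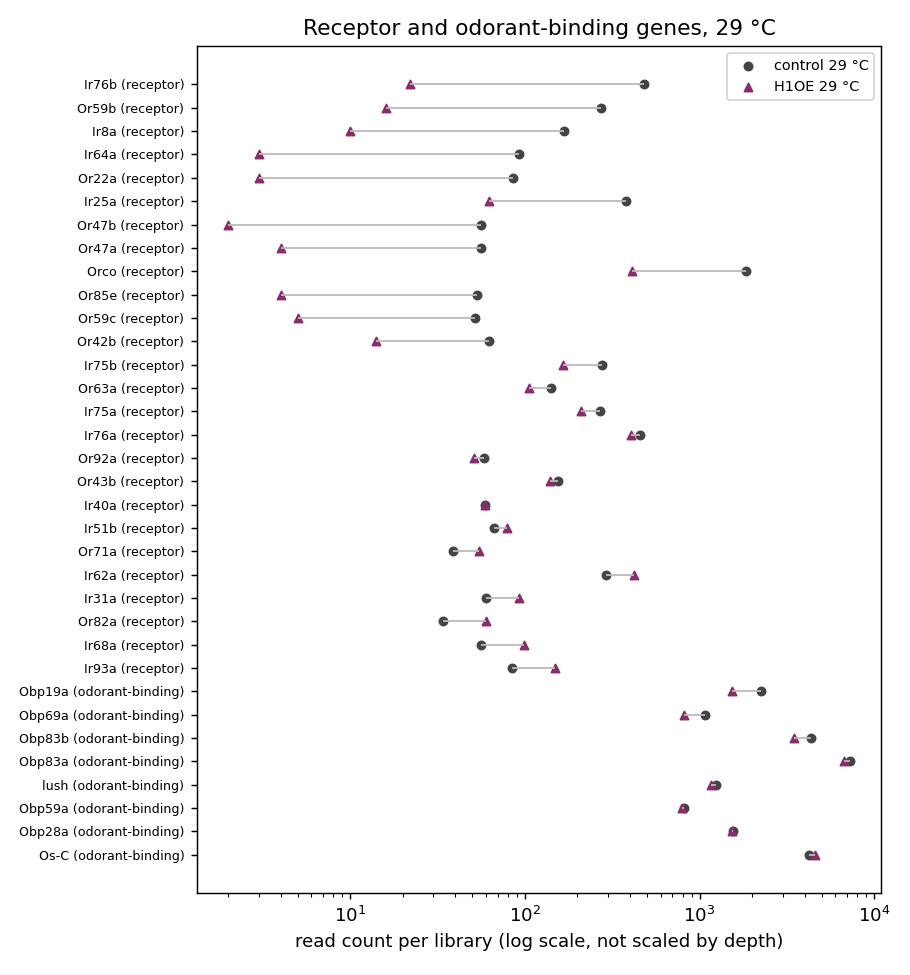
Read counts (x axis, log scale, 1 library per group) of 26 odorant and ionotropic receptor genes and 8 antennal odorant-binding genes in the 29 °C control (circles) and H1OE (triangles). Receptor genes such as Ir76b (481 and 22 counts) are far apart, whereas odorant-binding genes such as Obp83a (7294 and 6733) are close.

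Levodopa and H1OE at 29 °C shared lower antimicrobial and fat body genes. Lower past the size rule in both were 13 antimicrobial and 6 fat body genes, among them DptA, DptB, AttC, Lsp1alpha and fit, while the antimicrobial gene Drs fell in Levodopa and rose in H1OE. In all, 38 genes were higher and 69 lower in both among 10897 compared. Independent lists would share 1.91 and 6.64 genes, and unchanged groups simulated against the same control with the spread of the 25 °C columns shared 18.6 on average and 33 at most, against 107 observed. The simulation leaves out variation between fly samples, which would enter both comparisons through the control, so 33 is no upper limit for unchanged groups. Across genes the log2 fold changes had Pearson's r 0.458 (simulated 0.587) and Spearman's rho 0.416 (simulated 0.502), both below the simulated values. Their covariance was 0.0877, against a simulated 0.0384, a difference of 0.0493. The single control could not be split, so part or all of the excess may come from it. Amy-p, Drs, CG1673, Mdr50, phu and an unnamed locus passed in opposite directions, 6 genes against 7.12 for independent lists.

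**Figure D3:**
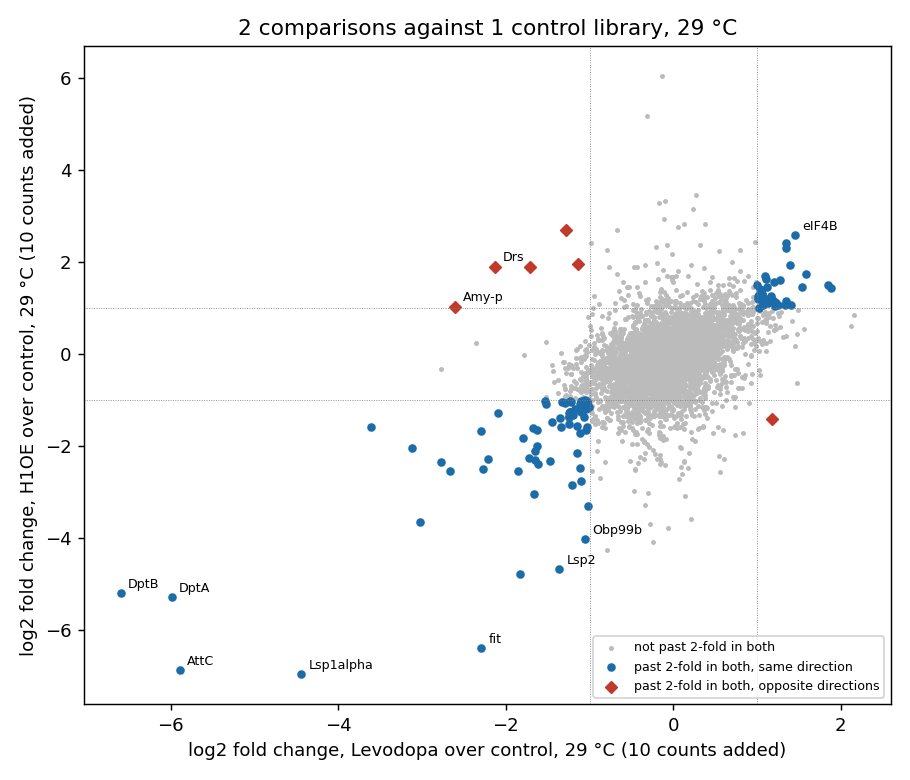
Log2 fold change in H1OE (y axis) against Levodopa (x axis) at 29 °C, each over the same single control library, with 10 counts added; each point is a gene and dotted lines mark 2-fold. Genes past 2-fold in both, 107 in the same direction and 6 in opposite directions, are coloured; DptA, DptB, AttC and Lsp1alpha lie at the lower left.

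Few genes passed under Levodopa at both temperatures, though more than independent lists would share. Among 10623 genes compared at both, 5 were higher and 14 lower in both, against 1.54 and 3.495 for independent lists, and 16 passed in opposite directions against 4.72. These numbers set edgeR calls at 25 °C against the size rule at 29 °C; with the size rule on summed columns at 25 °C, 1 gene was higher and 12 lower in both. Shared falls included Drs (-3.49 at 25 °C and -2.13 at 29 °C), Obp99b (-2.82 and -1.05), Dro (-1.44 and -3.03) and PGRP-SC2 (-1.01 and -1.83). DptA, DptB, AttC, AttD, edin, Lsp2 and tobi rose at 25 °C and fell at 29 °C. These genes were also lower in H1OE against the same single 29 °C control. Across genes Pearson's r was 0.129 and Spearman's rho 0.214. Levodopa at 25 °C and H1OE at 29 °C shared 18 higher and 36 lower genes, against 4.74 and 10.6 for independent lists. Another 26 passed in opposite directions there, against 14.3, with Pearson's r 0.185 and Spearman's rho 0.264. The excess over independent lists was therefore not particular to the 2 Levodopa comparisons. No test of the difference between temperatures was possible, since 29 °C had no replicates. The flies of the 2 tables also differed in a marker gene, though both controls are labelled wild type: the eye pigment transporter gene white had 0 to 3 counts per column at 25 °C and 2686 to 3531 per library at 29 °C. Akh had 1025 summed counts in control and 2120 in Levodopa at 25 °C, but 7, 5 and 4 in control, Levodopa and H1OE at 29 °C. For Mcad these were 3969 and 2140, and 8, 24 and 14. Whether genotype, tissue taken or temperature lay behind this was not tested.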

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

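The differences between temperatures below were not tested, because 29 °C had 1 library per group, and they were looked for after the single comparisons had been seen. Under Levodopa, 16 genes passed in opposite directions at 25 °C and 29 °C; the 8 given here also met the count minimum of the named-gene rule in both tables and had no overlap of columns at 25 °C.

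The peptide genes DptA and DptB rose by 1.96 and 1.16 on the log2 scale at 25 °C and fell by 5.99 and 6.60 at 29 °C, differences of -7.94 and -7.76. AttC went from 427 to 1764 summed counts at 25 °C and from 6267 to 104 at 29 °C, a difference of -7.66. AttD, on 12 and 110 counts at 25 °C and 68 and 7 at 29 °C, differed by -5.17. For edin, with 90 and 224 counts at 25 °C and 56 and 0 at 29 °C, the difference was -3.82. Lsp2, the larval serum protein gene, had 31 and 324 counts at 25 °C but 20606 and 8698 at 29 °C, a difference of -4.46. Likewise tobi had 225 and 611 counts at 25 °C and 54986 and 27894 at 29 °C, a difference of -2.26. CG1773 went the other way, from 431 to 176 counts at 25 °C and from 41 to 102 at 29 °C, a difference of 2.61. In H1OE at 29 °C, DptA, DptB, AttC, AttD, edin, Lsp2 and tobi had 19, 65, 50, 5, 4, 906 and 9253 counts. All of these were lower past the size rule against the same single control. A high level in that control library therefore cannot be told apart from a Levodopa effect that differs with temperature. The white gene also differed between the 25 °C and 29 °C flies. The insulin, AKH and starvation list had medians of 0.43 and -0.17, a difference of -0.60.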

How the results depend on the processing

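The alternatives called protein-coding genes, mitochondrial genes left out, columns summed and length trend removed were chosen after the data were seen. Levodopa at 25 °C called 609 genes. This became 399 with a filter of 50 counts, 118 at 4-fold, 2503 at 1.5-fold, 241 with a pseudocount of 50 counts, 387 with protein-coding genes only, and 289, 118 and 348 with limma on log2(FPKM + 1), log2(FPKM + 5) and rescaled FPKM. The 295 genes of Levodopa at 29 °C became 82 with a filter of 50 counts, 815 and 39 with pseudocounts of 1 and 50, 20 at 4-fold, 1090 at 1.5-fold, 605 and 57 with FPKM pseudocounts of 0.1 and 5, 93 with an FPKM filter of 5, and 184 with protein-coding genes only. The 808 genes of H1OE became 400, 1443, 256, 103 and 2070 under the first 5 of these settings, 166 with an FPKM pseudocount of 5 and 280 with an FPKM filter of 5. The 107 genes shared by H1OE and Levodopa at 29 °C became 38 with the filter of 50 counts and 356 and 25 with pseudocounts of 1 and 50. The 19 genes shared by Levodopa at both temperatures became 12, 40 and 6 under the same settings and 29 with FPKM. Stricter filters and thresholds and larger pseudocounts lower such counts by construction, and for the FPKM settings the cause was not tested.

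Leaving out 1 column at a time at 25 °C gave 489 to 559 genes, with 137 to 190 higher in place of 238, the lone column being assumed to vary like the others; Acox57D-d (-0.99) and Hsp70Aa (0.99) each lost their call once, and Ilp2, tim and S-Lap2 gained one in at least 1 of these fits. The size rule on summed columns gave 429 genes, 105 higher and 324 lower. Pairing the columns by number (replicate block) gave 579 genes and changed no call of a named gene, and deviations of same-numbered columns correlated at -0.0177 over 7113 genes, so the numbers were not treated as pairs. No paired analysis was possible at 29 °C because each sample had 1 column. Removing the length trend gave 663 genes at 25 °C, 536 higher and 127 lower, and ended the calls of ND-B12 (-0.58), ATPsynO (-0.60), RpLP2 (-0.63), RpS14b (-0.61), Mcad (-0.83), GstE9 (-0.74) and NimB4 (-0.82), whose folds it lowers as short genes; total-count scaling ended those of ND-B12 (-0.99) and ATPsynO (-0.96). DESeq2 shared 455 calls with edgeR. Total-count scaling shifted log2 fold changes by 0.05 and 0.07 at 29 °C.

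Camera called 11 lists with the preset correlation, 0 with an estimated one (smallest adjusted p = 0.306), 6 with a filter of 50 counts and 8 to 10 with a column left out; fry called 24 of 26. The estimated version rests on few degrees of freedom, so its lack of calls does not measure correlation between genes. The synaptic list, with an estimated correlation of -0.025, below the preset 0.01, was not called there either. Other lists had estimates above the preset, among them 0.428 for ribosomal proteins, 0.211 for fat body, 0.184 for heat shock and 0.0604 for oxidative phosphorylation. If these estimates hold, the adjusted p of camera with the preset correlation is too small for those lists. The median of the oxidative phosphorylation list in Levodopa at 29 °C changed from -0.11 to 0.00 (-0.00287) and that of ribosomal proteins to 0.0125 with the length trend removed, as short genes have lower values. The digestive median in H1OE turned to -0.12 with a filter of 50 counts and to -0.0364 without a filter, the cause not being tested. Of the other list results under their alternatives 298 stayed outside the random lists in the same direction and 13 moved inside (in the serotonin and octopamine, clock, heat shock and digestive lists at 25 °C, the fatty acid synthesis and detoxification lists of Levodopa at 29 °C and the synaptic, digestive and haemocyte lists of H1OE). With the length trend removed the neuropeptide list (0.34) moved outside the random lists at 25 °C, as did the fatty acid synthesis (-0.45), lipid carrier (-0.33) and haemocyte (-0.30) lists; at 29 °C so did the dopamine, lipid carrier and muscle lists of Levodopa and the ribosomal (0.15), dopamine, insulin and glial lists of H1OE. For single genes, 3256 results stayed on their side or within their interval and 362 moved beyond the counting interval. At 25 °C, 61 results lost and 38 gained a call. Calls lost or gained at 29 °C are not in these 2 numbers. At 4-fold 11 of 24 named genes of Levodopa and 11 of 36 of H1OE lost theirs, and at 1.5-fold 8 of 41 and 11 of 31 gained one. The size rule at 29 °C contains its own count minimum, so leaving out the filter changes no count of genes there, though it changes gene lists, and FPKM filters at 25 °C and FPKM pseudocounts for overlaps and lists were not run.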

Other observations

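All tests in this part were chosen after the results they bear on had been seen, except the test for a general background of reads.

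Transposable element insertions leaned upwards in Levodopa at 25 °C. Of 792 tested, 108 rose and 4 fell, with a median log2 fold change of 0.71 (215 and 5 with the length trend removed, 149 and 2 with total-count scaling, 75 and 0 with DESeq2, and 59 and 1 of 213 with a filter of 50 counts), whereas 89 of 10286 protein-coding genes rose and 352 fell. Non-coding RNAs leaned upwards too, with 37 higher and 14 lower of 627 (median 0.31). Chromosome 4, which is rich in heterochromatin, had 38 of 326 features higher (11.7%, median 0.64) and the other large arms 1.23 to 1.91%. Its 79 protein-coding genes had 0 past the thresholds, but 70 were positive, with a median of 0.52, and 0.26 with the length trend removed, against -0.07 and 0.00 for protein-coding genes elsewhere. In Levodopa at 29 °C 28 insertions were higher and 32 lower of 620, and in H1OE 74 were higher and 38 lower of 663. For non-coding RNAs these were 19 and 20 of 434 in Levodopa at 29 °C, and 59 and 26 of 476 in H1OE. Chromosome 4 features higher at 29 °C were 3.81% in Levodopa (other large arms 0.84 to 1.28%) and 4.78% in H1OE (2.38 to 4.55%), with protein-coding medians of -0.03 and 0.01. Insertions are repeats, so reads can be shared between copies.

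In H1OE 7 of 17 measured genes of the mitochondrial genome fell and 0 rose, with a median of -0.91. Counts of mt:ND1 went from 26848 to 9977, of mt:ND2 from 4220 to 1452 and of mt:ATPase6 from 50795 to 23493. The most abundant members moved less, mt:CoI from 516090 to 530726 (-0.14), mt:lrRNA by -0.14 and mt:CoIII by -0.23, and the share of all counts went from 5.23 to 4.47%. These genes were chosen after their values were seen.

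The shift of gene classes in Levodopa at 25 °C, with energy and ribosomal genes lower and synaptic genes higher, went with gene length; that of insertions did not, their median rising to 0.95 with the trend removed. For the energy and ribosomal genes a length trend shared by all genes is argued against as the whole cause. With that trend removed the median nearest 0, of ribosomal proteins, went from -0.89 to -0.45 (bootstrap SE 0.02). This was still below the random lists' limit of -0.34. Those lists were matched on mean expression and not on length, so a steeper trend among short, highly expressed genes is not excluded. For the synaptic genes length cannot be told apart from another cause, since their median went from 0.47 to 0.0778 (bootstrap SE 0.05), within 2 SE of the limit of 0.04. A general background of reads at features not expressed in heads cannot be told apart either, as protein-coding genes and insertions went apart. Protein-coding genes with at most 2 counts in each 29 °C library had a median of -0.29 (bootstrap SE 0.07) over the 284 with at least 10 counts at 25 °C, against the prediction. With minimums of 3 and 1 counts, tried afterwards, it was -0.11 (SE 0.09) and 0.14 (SE 0.09). Such insertions had 0.51, 0.41 and 0.70 at minimums of 10, 3 and 1. Long non-coding RNAs had 0.04 (SE 0.23), 0.31 and 0.72 at the same minimums. A difference in RNA or library quality between the samples and a response to Levodopa both stay open, as each sample is 1 labelled unit.

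A set of 13 genes, picked because their log2 fold change was -7 or lower, was near 0 in Levodopa at 25 °C and abundant in its control, CG16826 at 1929 CPM. Midgut tissue in the control heads is argued against, because 27 Jonah and trypsin genes together had at most 76 counts in a control column. Other tissue taken along with the heads was not tested, and the set includes LysP of the digestive list, with 1206 counts in control and 10 in Levodopa. In the untreated 29 °C control these genes had at most 3.40% of their 25 °C control level, so the 25 °C control could be the group that stands apart. As the white gene differs between the tables, this and a response to Levodopa cannot be told apart. The highest count of the set in the 29 °C control was 13, too few to test the response there.

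The lower chemosensory receptor genes in H1OE could come from heads without antennae, from a loss of all such neurons alike, from a change in some of them, from the genetic background or from H1. Missing antennae are argued against by 8 antennal odorant-binding genes, whose median log2 fold change was -0.29 (SD 0.22). A loss of all alike is argued against because the SD of log2 fold changes over the 26 receptor genes was 3.96 times (bootstrap SE 0.61) that of the same genes in Levodopa at 29 °C, with values from -4.09 to 0.59; a change in some of them was not tested. The genetic background cannot be told apart from H1, nor can driver and rearing temperature, which are not matched by label. The body colour gene yellow, with a log2 fold change of 2.95, had 5 counts in the control and 115 in H1OE. Its counts also differed within 25 °C (63 and 84 in the control columns, 28 and 23 in Levodopa). The white gene was alike in the 29 °C control and H1OE, at 2686 and 2832 counts, so neither gene settles the background.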
